A study of Homo sapiens with 4 samples.

How the data were processed

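U87MG is an established human glioblastoma cell line. Its cells were kept for 24 h in 1 of 4 conditions: DMSO as the control, 10 µM mycophenolic acid (MPA), 100 µM guanosine, or both compounds together. Total RNA was made into biotin-labelled target and hybridised to Affymetrix PrimeView arrays, which read mRNA near the 3' end. There was 1 array for each condition, so 4 arrays in all, and each array's condition came from its label.

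The deposited values are probe set intensity values on the linear scale, made by RMA (background correction, quantile normalisation and median polish of the probes) per the labels, which name the signal but give no settings. The software, its version and the array annotation used by the authors are not given in the sources used here. Quantile normalisation forces the arrays toward one distribution, so a change in the total amount of mRNA per cell would not be visible. The median intensity was 63.0 on the control array, 64.5 with MPA, 62.5 with guanosine and 61.8 with both.

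The log2 of each value was taken first. Of 49395 probe sets, 44994 had 1 gene symbol in the platform's gene table, 1832 had several, and 2569 were not listed there and are unnamed here. The 102 control probe sets, of which 96 were not listed, entered no gene. The symbols were checked through Entrez IDs against a RefSeq gene table, which held 44967 of the 44994, and 0 symbols changed. A gene was represented by its probe set with the highest mean over the 4 arrays; probe sets ending in _x_at, whose probes can bind several genes, were used only for the 601 genes with no other. This gave 18132 genes. A dim-gene floor was set at the median of all non-control values, 63.0 in signal or 5.98 on the log2 scale. A gene entered a comparison when the brighter of its arrays was at or above this floor, and 11019 genes reached it on at least 1 array. Where the dimmer array lay below the floor, the fold of a gene named for its size is given against the floor as "at least"; members of lists keep their measured difference, and the text says where an array was below the floor. No genome coordinates are given, since no build was used.

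The 5 comparisons were MPA against control, guanosine against control, both compounds against control, both against MPA, and both against guanosine. With 1 array per condition there are no replicates, so no spread between cultures could be measured, no p-value is given, and the number of arrays limits the precision of every value. Genes were counted at a fixed size of 2-fold on measured values, also where 1 of the arrays was below the floor. A total of 40 gene lists was fixed before the data were examined. Each list's median log2 difference, over members at or above the floor on at least 1 array, was placed among 10000 random lists of the same size matched on mean expression in 20 bins. That percentile describes these arrays and is not a test of the conditions. Members of lists were also counted at 1.5-fold. About 2 of 40 lists would fall outside the middle 95% of random lists by chance.

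The named genes followed a rule also fixed beforehand. For MPA against control they are the 12 highest and 12 lowest among genes at least 2-fold different, and for other comparisons 6 and 6, provided that the median of a gene's other probe sets above the floor had the same sign. Within a list they are the highest and the lowest member and up to 2 more of each. A set of genes of guanine nucleotide synthesis, nucleolar function and the cell cycle was always to be named: IMPDH1, IMPDH2, GMPS, HPRT1, NPM1, NCL, CDKN1A, MDM2, MYC, POLR1A, POLR1B, POLR3A, POLR3G, RRN3 and UBTF. GNL3 belonged to this set and is not analysed here, and 1 further gene of the set is not reported here. Genes named outside the rule are marked as chosen after their values were seen.

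Correlations between comparisons were computed across genes, which are not independent replicates. Where 2 comparisons shared an array, the correlation and covariance of simulated unchanged arrays with log2 noise of SD 0.0703 are given beside the observed ones. That SD was derived from both compounds against guanosine, the closest pair of arrays, and given to every array alike. A shared array that deviated by more than this would raise the size of the correlation and covariance. The counting step was tested on simulated data for MPA against control over 10652 genes: 100.0% of 50 genes with a log2 change of 1.5 and 100.0% of 50 with -1.5 were counted, 0 of 100 with changes of 0.585 in either direction, and 0 unchanged genes. The assumed noise of that test, SD 0.0672, was also derived from both compounds against guanosine. It therefore rests on that pair of cultures alone and can understate differences between other cultures.

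Alternatives set beforehand were no filter on dim genes, a floor at the 75th percentile, the median of a gene's probe sets, only genes whose probe sets above the floor all had 1 direction, _x_at probe sets kept, cyclic loess on top of RMA (3 iterations), and a 3-fold threshold. A 1.5-fold threshold, values below the floor raised to it, the guanosine array as reference for MPA, and the mean of the other 3 arrays as reference were added after seeing the data. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 for the loess step.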

Results

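The series measured gene expression in U87MG glioblastoma cells after 24 h with or without MPA and guanosine. MPA blocks IMP dehydrogenase, the enzyme that commits IMP to guanine nucleotide synthesis, and guanosine can be salvaged into guanine nucleotides without that enzyme. The title names IMP dehydrogenase-2 and the nucleolus, so the comparisons ask what MPA does to these cells' mRNA and whether guanosine alters it. Each of the 4 conditions was read on 1 array, and a difference below is between 2 arrays with no replicate check. Across all probe sets, the log2 values of the control array correlated at r = 0.990 with the MPA array and at 0.997 with the guanosine array and with the array of both compounds. The guanosine array and the array of both compounds correlated at 0.998.

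MPA against control gave the largest differences from control in the series. The p53 target genes, a list of stress response and cell cycle arrest genes, were higher on the MPA array, and genes of DNA replication, mitosis and ribosome biogenesis were lower. GDF15, a stress cytokine, had a signal of 3917 with MPA and 396.8 in the control, 9.87-fold higher. The cell cycle inhibitor CDKN1A was 3.01-fold higher, at 4961 against 1649, and the ubiquitin ligase gene MDM2 was 2.18-fold higher. MYC, a driver of growth and of ribosome synthesis, had a signal of 284.2 with MPA and 791 in the control, a log2 difference of -1.48. The list of MYC target genes outside the nucleolus had a median of -0.13 at percentile 11.6, inside the range of random lists, with 12 of 19 genes lower. The MYC network list had a median of 0.06. Among 10951 genes compared, 189 were at least 2-fold higher and 156 at least 2-fold lower.

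SCN2A, a sodium channel gene, had the largest measured difference. Its control signal was below the floor, so it was at least 4.48-fold higher and its rank is uncertain. The genes next most raised over control were GDF15, TP53INP1 (8.56-fold), TP53I3 (7.84-fold), SUGCT (6.79-fold), GDF5 (6.48-fold), SESN1 (5.52-fold), RRAD (5.45-fold), the antisense transcript GAS6-AS1 (5.23-fold) and TNFSF9 (5.22-fold). PTCHD4 was at least 3.99-fold and SPATA18 at least 4.59-fold higher, both from below the floor in the control. For TP53INP1 the difference stood on 1 probe set, and its other probe set above the floor differed by 0.08. One of the other 2 probe sets of GDF15 differed by 3.29, and the dimmer one by 0.29.

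The genes furthest below control were INF2, an actin-assembling formin (log2 -2.65), cyclin E2 gene CCNE2 (-1.96), RBM14 (-1.90), UHRF1, which maintains DNA methylation at replication (-1.81), HBEGF (-1.75), the histone chaperone subunit CHAF1A (-1.73), GINS2 (-1.66), the cell cycle phosphatase CDC25A (-1.63), CDCA7 (-1.63) and the replication licensing factor CDT1 (-1.60). HAS2 and LIN9 had MPA signals below the floor and were at least 1.27-fold and at least 1.32-fold lower. The INF2 value came from 1 probe set, and 2 others above the floor differed by -1.02 and -0.20.

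All 35 measured p53 targets above the floor were higher on the MPA array, 32 by at least 1.5-fold and 23 by at least 2-fold. Their median was 1.24, and 0 of 10000 random lists reached it. GDF15, TP53INP1 and TP53I3 led the list, and the smallest difference was that of PERP, 0.21. The G1 list, of cyclins and their inhibitors, held CDKN1A at 1.59 but had a median of -0.35, with CDK2 at -0.96. DNA replication and S phase genes were lower in 41 of 41 cases, 31 by at least 1.5-fold, with a median of -0.99 that lay below all random lists. CCNE2, UHRF1 and CHAF1A led that list, and PCNA differed by -0.03. All 36 G2 and mitosis genes were lower, 22 by at least 1.5-fold, with a median of -0.71; BUB1B stood at -1.33, KIF23 at -1.17 and CCNB1 at -1.14, and CDK1 at -0.13. Against the guanosine array in place of the control, the G2 and mitosis median was -0.31.

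Ribosome biogenesis and RNA polymerase I genes were lower as groups. Of 60 ribosome biogenesis factors, 59 were lower and 21 by at least 1.5-fold, with a median of -0.43 below all random lists; BYSL was at -1.08, BOP1 at -0.99 and NOLC1 at -0.96, and NOP10 at 0.15. All 15 genes of the RNA polymerase I machinery, which transcribes the large ribosomal RNA precursor, were lower, 5 by at least 1.5-fold. Their median was -0.41, at percentile 0.06, or -0.29 when each gene was the median of its probe sets. POLR1E was at -1.23 and TAF1A at -1.04, the latter below the floor with MPA. POLR1A differed by -0.59, UBTF by -0.38, RRN3 by -0.34 (-0.09 for its other probe set above the floor) and POLR1B by -0.06. The RNA polymerase III machinery, which makes transfer RNA and 5S RNA, had a median of -0.07 over 24 genes at percentile 30.9, with POLR3K at -0.75, POLR3G at -0.56, POLR3A at -0.06 (-0.46 for its other probe set above the floor) and SNAPC5 at 0.65. The list named beforehand as GTP-sensing and other nucleolar GTPases had a median of -0.20 over 10 genes at percentile 13.7, inside the range of random lists. Of the 10, 9 were lower, with TSR1 at -0.76, GTPBP4 at -0.64 and DRG2 at 0.08. Whether each member is nucleolar was not checked. The nucleolar proteins NPM1 and NCL differed by -0.26 and -0.48. The 59 ribosomal protein genes had a median of -0.01 that became 0.03 after cyclic loess, and only RPL27A passed 1.5-fold, at -1.29 on a single probe set that was below the floor with MPA.

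In purine metabolism, IMPDH2 was higher on the MPA array, 9168 against 7120 (log2 0.36, and 0.41 and 0.46 for its other probe sets). IMPDH1 was at -0.37 on its main probe set and 0.17 on another, GMPS at -0.64 and the salvage enzyme HPRT1 at -0.36. The guanine nucleotide synthesis and salvage list, which holds these genes, had a median of -0.36 over 6 genes at percentile 2.06, with 4 lower and 2 higher. The median of 8 de novo purine synthesis genes was -0.29 at percentile 4.0, with GART at -0.80, PAICS at -0.79 and PPAT at -0.64 and PFAS at 0.16. The pyrimidine and deoxynucleotide list had a median of -0.45 with 13 of 14 genes lower, among them UCK2 at -0.69; the exception, RRM2B at 1.26, is a p53 target. Cholesterol synthesis and uptake genes had a median of -0.25 over 18 genes, with HMGCS1 at -0.94 and TM7SF2 at 0.61.

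Groups that were higher besides the p53 targets had smaller medians. The lysosome and autophagy list had 21 of 22 genes higher and a median of 0.31, above all random lists, with NEU1 at 1.17, GPNMB at 1.09 and LAMP2 at -0.28. The oxidative stress list had a median of 0.30 with members on both sides, TXNRD1 at 0.80 and GCLM at -0.66. Inflammatory and NF-κB target genes had a median of 0.29, led by IL1A (0.85) and CXCL8 (0.72), with TNFAIP3 lowest at -0.34. Interferon-stimulated genes had a median of 0.27, led by TRIM22 (1.95), which the p53 list also holds. Of these 27 genes, 9 were lower, IFI44 the most at -0.92. Extracellular matrix and TGF-β targets had a median of 0.22, with ACTA2 at 1.55, TIMP3 at 1.30 and COL4A2 at -0.70. The integrated stress response list divided: DDIT3 was at 1.29 and ATF3 at 1.02, while VLDLR was at -1.04 and SHMT2 at -0.60, for a median of -0.08. The immediate early list also divided, with FOSL1 at -1.25, SPRY2 at -1.20 and FOSL2 at 0.98.

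Among markers of other cell types, ERG, of the endothelial and pericyte list, had a signal of 123.4 with MPA and of 43.5 in the control; the latter is below the floor of 63.0, against which the difference does not reach 2-fold. That list had a median of -0.15 over 6 genes, with CSPG4 at -0.68. The astrocyte, leukocyte, epithelial, and neuron and oligodendrocyte lists held 0 genes past 2-fold and 1 each past 1.5-fold. The astrocyte median was 0.32 over 8 genes, led by GLUL (0.72), with SLC1A2 lowest at -0.30. The epithelial median was 0.21 over 6 genes, led by EPCAM (0.88, below the floor in the control). KRT18 was lowest there at -0.46, below the floor with MPA. The neuron and oligodendrocyte median was 0.21 over 9 genes, led by SNAP25 (0.71), with TUBB3 lowest at -0.18. With the floor at the 75th percentile, the neuron and oligodendrocyte median was -0.0062. Only 3 of 11 leukocyte markers were above the floor, with a median of 0.08 and CD68 at 0.64. RNA quality readings of the MPA array lay close to those of the others: the ACTB 3' minus 5' log2 value was 1.72 with MPA, 1.82 in the control, 1.77 with guanosine and 1.89 with both, and the GAPDH value was 0.09, 0.13, 0.09 and 0.11. The poly-A spike-in transcripts, added to the RNA before labelling, were lower on the MPA array in 12 of 12 probe sets, with a median of -0.29, and higher by 0.22 with guanosine and 0.27 with both. Background probes with a GC count of 20 or more were at 0.26 on the MPA array and -0.08 and -0.15 on the others. The GC content of list members' probes was not checked, and the random lists were not matched on it.

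Guanosine against control asks what the nucleoside does by itself. IMPDH2 had a signal of 4067 with guanosine and 7120 in the control, a log2 difference of -0.81, with -0.89 at both other probe sets. Genes of hypoxia and glycolysis were higher in 24 of 28 cases with a median of 0.23, above all random lists, led by HK2 and NDRG1 (both 0.69) and ANKRD37 (0.62). Both compounds against MPA shares no array with this comparison. There the list median was 0.16 at percentile 94.4, inside the range of random lists, with 18 of 28 higher. NDRG1 differed by 0.51 there, ANKRD37 by 0.79 and HK2 by -0.08. HK2 was also higher with MPA than in the control, by 0.57. The glycolytic enzyme genes of the list were mixed. GAPDH (0.01), LDHA (0.01) and ENO1 (-0.0009) were near 0, PGK1 (0.21) and PFKP (0.16) were higher, and PFKM was lowest at -0.15. All 36 G2 and mitosis genes were lower with a median of -0.40, below all random lists, KIF20A at -0.72 and CDC20 at -0.68; DNA replication genes had a median of -0.14. The 5 polyadenylated histone genes had a median of -0.40, also below all random lists, with H2BC12 at -0.65, H2AC6 at -0.59 and H2BC21 at 0.29, the last below the floor on both arrays. In the integrated stress response list, NUPR1 (0.80), asparagine synthetase gene ASNS (0.73) and the serine synthesis gene PSPH (0.60, below the floor in the control) were higher. NUPR1 was also higher with MPA than in the control, by 0.96. In both compounds against MPA, NUPR1 differed by -0.09, ASNS by 1.07 and PSPH by 1.11, the last from below the floor with MPA. DDIT3 was lowest at -0.25, and the list median was 0.09. MYC differed by 0.06, CDKN1A by -0.27 and MDM2 by 0.13.

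Of 10663 genes compared, 0 were at least 2-fold higher with guanosine and 1 at least 2-fold lower, the centriole gene SCLT1, whose guanosine signal was below the floor, so that it was at least 1.46-fold lower. At 1.5-fold the counts were 39 and 14. For 28S ribosomal RNA, only the middle and 5' control probe sets were summarised, 2 in number. Their median differed from control by -0.86 with guanosine, -0.60 with MPA and -0.91 with both on the log2 scale. The 18S probe sets differed by 0.17, -0.02 and 0.08. The arrays are made to read mRNA, and whether these control signals follow the amount of ribosomal RNA was not checked. In these 28S probe sets and in the G2 and mitosis list, the control array was above all 3 others.

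Both compounds against guanosine asks what MPA did when guanosine was present, and it shares no array with MPA against control. The p53 targets had a median of 0.02, DNA replication genes 0.03, ribosome biogenesis factors 0.02 and the RNA polymerase I machinery 0.05. CDKN1A differed by 0.04, GDF15 by 0.05, MYC by -0.09, CCNE2 by 0.05 and IMPDH2 by 0.06. None of 10599 genes passed 2-fold in either direction (0 higher and 0 lower), and 2 passed 1.5-fold, AP1S1 at -0.76 and FER1L6 at -0.61, the latter below the floor with both compounds. HIVEP1 was the highest, at 0.51; these 3 genes were chosen after their values were seen.

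The 189 genes at least 2-fold higher with MPA alone had a median log2 difference of 1.29 there and of 0.04 when guanosine was present, where they lay between -0.39 and 0.32. The 156 lower genes had medians of -1.17 and 0.02, and with guanosine present they lay between -0.32 and 0.28. Across 11019 genes, the MPA difference without guanosine and that with guanosine had r = -0.01 and Spearman's rho = -0.02. No gene was at least 2-fold different in opposite directions in these comparisons (0 genes). The hypoxia and glycolysis list had a median of -0.06 here, below all random lists.

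**Figure D1:**
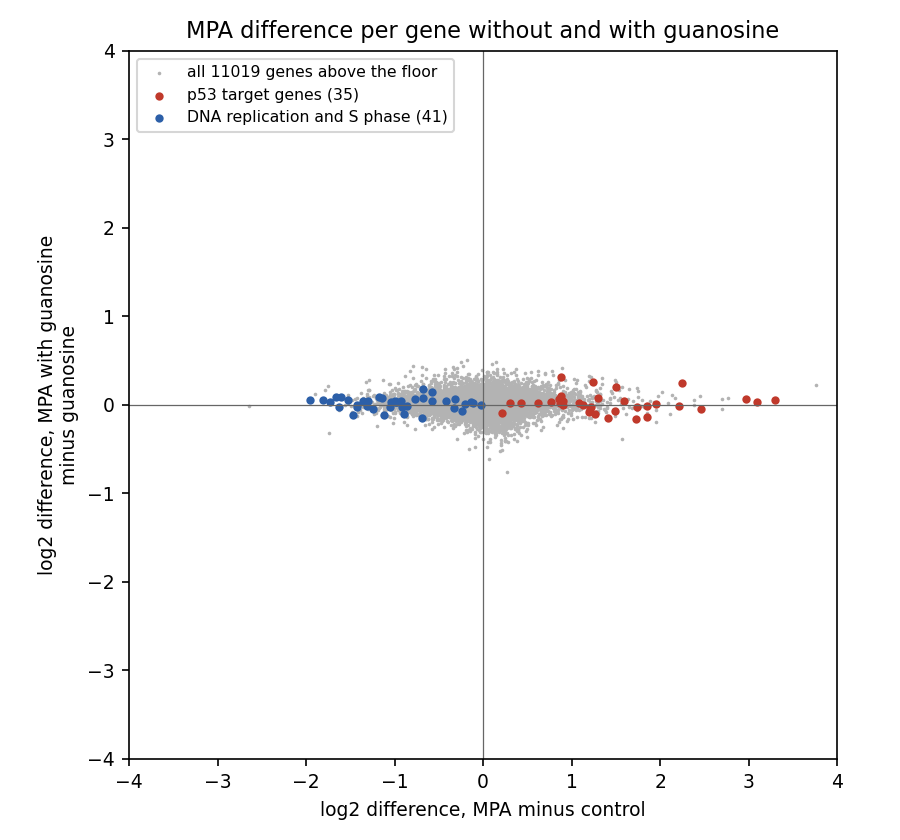
Each point is a gene above the floor (11019 genes); the horizontal axis is the log2 difference MPA minus control and the vertical axis the log2 difference of both compounds minus guanosine, each between 2 arrays. The 35 p53 targets lie to the right (median 1.24) and the 41 DNA replication genes to the left (median -0.99), and both lie near 0 on the vertical axis (medians 0.02 and 0.03).

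Both compounds against MPA asks what guanosine did in the presence of MPA. GDF15 was 10.8-fold lower, TP53I3 8.63-fold, GDF5 8.53-fold, TP53INP1 6.63-fold and the polo-like kinase PLK2 6.35-fold lower with guanosine added, and SCN2A at least 4.48-fold lower. INF2 was 7.76-fold higher, the coagulation factor receptor gene F3 4.76-fold, ZC3HAV1L 4.09-fold, RBM14 4.04-fold and CCNE2 3.77-fold higher, and FAM117B at least 1.97-fold higher. IMPDH2 was 2.17-fold lower. The p53 targets had a median of -1.27 with 35 of 35 lower, DNA replication genes 0.82 with 37 of 41 higher, the RNA polymerase I machinery 0.49 with 15 of 15 higher, ribosome biogenesis factors 0.43 and G2 and mitosis genes 0.31.

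Among 10956 genes, 179 were at least 2-fold higher and 170 at least 2-fold lower with both compounds than with MPA alone. Because the MPA array is in both comparisons, these differences and those of MPA against control lean in opposite directions even without an effect: r across genes was -0.92, simulated unchanged arrays gave -0.51, and the covariance was -0.165 against a simulated -0.0050. Of the genes higher with MPA, 139 were at least 2-fold lower again here, and of those lower with MPA, 109 were at least 2-fold higher, 1 of which, LIN9, was below the floor on both of these arrays; part of this can come from the shared array.

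Both compounds against control compares the combined treatment with untreated cells. G2 and mitosis genes had a median of -0.39, hypoxia and glycolysis genes 0.15, and IMPDH2 differed by -0.75; with guanosine alone these values were -0.40, 0.23 and -0.81. The p53 targets had a median of 0.02, which was -0.01 after cyclic loess, and MYC differed by -0.02. Among 10672 genes, 0 were at least 2-fold higher and 0 at least 2-fold lower; 50 and 18 passed 1.5-fold. The differences from control of guanosine alone and of both compounds had r = 0.83 across genes, where simulated unchanged arrays with a shared control gave 0.49, and a covariance of 0.0233 against 0.0048. A control array that deviated by more than the simulated noise would raise both values too.

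**Figure D2:**
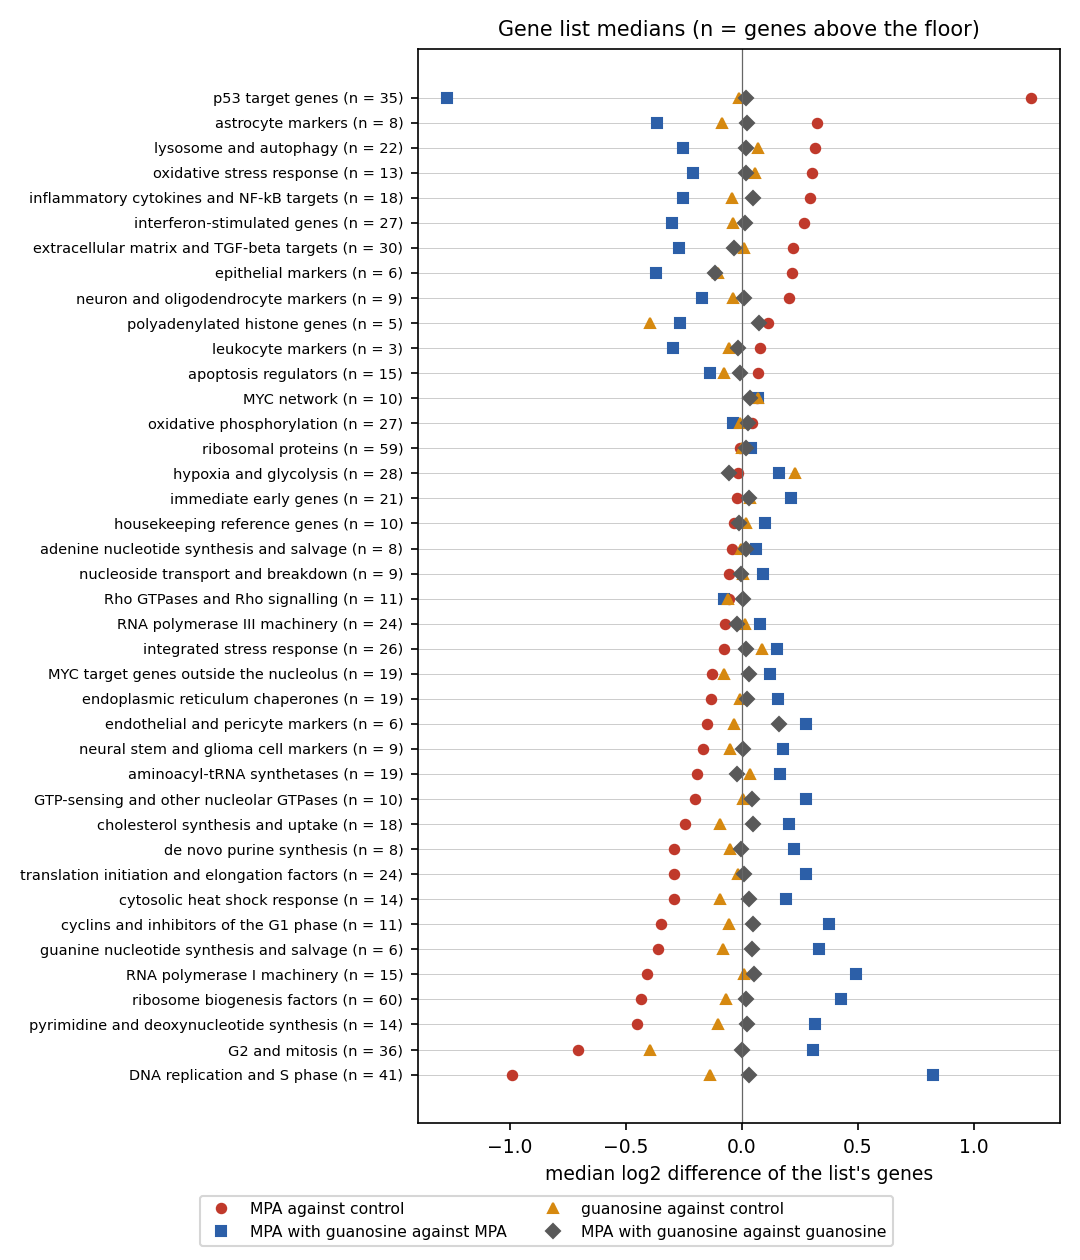
Each mark is the median log2 difference of a gene list's members above the floor, for 4 comparisons, ordered by MPA against control. The lists spread from -0.99 to 1.24 in MPA against control and lie between -0.12 and 0.16 in both compounds against guanosine, and G2 and mitosis (-0.40), polyadenylated histone genes (-0.40) and hypoxia and glycolysis (0.23) stand furthest from 0 in guanosine against control.

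**Figure D3:**
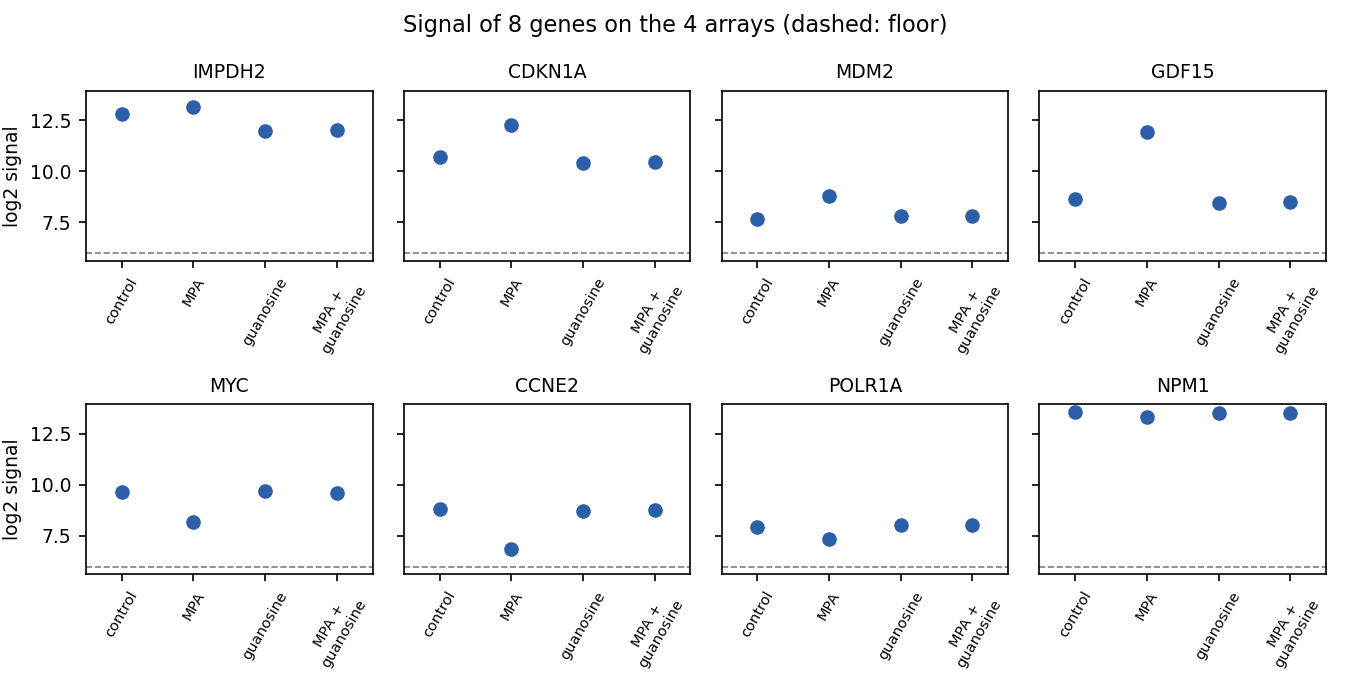
The log2 signal of 8 genes on each of the 4 arrays, 1 point per array, with the floor of 5.98 dashed. CDKN1A, MDM2 and GDF15 are highest and MYC and CCNE2 lowest on the MPA array, while IMPDH2 is lower on both arrays with guanosine, at 4067 and 4228 in linear signal.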

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

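All tests of explanations in this part were chosen only after the results were seen; the genes and probe sets below were picked by fixed sizes.

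Guanosine was compared with no guanosine once without MPA and once with it, on separate arrays, and 5 genes differed by at least 1.5-fold in opposite directions, against 19 in the same direction; 3 and 13 of these were above the floor on all 4 arrays. The opposition itself was not tested, since there are no replicates. The histone gene H2BC12 differed by -0.65 without MPA and 0.77 with it, a gap of 1.42; the chromatin gene HMGB3 by -0.74 and 0.59 (gap 1.33) and the non-coding gene DLEU2 by -0.67 and 0.91 (gap 1.58). For KLHL24 and the histone demethylase gene KDM7A, which differed by -0.996 and -0.82 with MPA, the control was below the floor, so that their gaps of -1.72 and -1.46 rest on a control value not above background, and the size of the difference without MPA is uncertain. With MPA alone, H2BC12, HMGB3 and DLEU2 were below control (-1.43, -1.39 and -1.32); these values share the control array with those of guanosine alone.

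Among 4305 probe sets that carry no single gene symbol and enter no gene count, 2022 were above the floor; 28 of them were at least 2-fold higher with MPA than in the control, the largest at 2.87, and 32 at least 2-fold lower. With guanosine present, 0 of the 28 were 2-fold higher and their median was 0.06.

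The differences of MPA against control were absent when guanosine was present. Degraded RNA on the MPA array is argued against by the ACTB 3' minus 5' value of 1.72, the lowest of the 4 arrays. A distortion blind to gene function that depends on expression level is argued against by 2 list medians, 1.24 (p53 targets) and -0.99 (DNA replication). These lay beyond all 10000 random lists, which were matched on expression but not on GC content. High-GC background probes differed by 0.26 on the MPA array, and a distortion tied to GC content was not tested. Of the 279 2-fold genes in no list, errors of single probe sets are argued against only for the 115 with another probe set above the floor: in 97.4% of these the others went the same way, against 76.3% among genes under 1.5-fold, although probe sets of a gene can share probes. Open stays that the culture given both compounds held no active MPA: the correlation of -0.014 across genes is what that predicts, and also what guanosine making up for blocked guanine nucleotide synthesis predicts. No value here separates these 2 readings.

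Guanosine alone and both compounds differed from control alike. A deviating control array alone is argued against for the 39 genes at least 1.5-fold higher with guanosine. Their median was 0.69 with guanosine and 0.69 with both compounds, values that share the control array. With MPA it was 0.10, and 25 of the 39 were higher. Against the MPA array, both compounds gave 0.51. A control low in these genes together with a lowering of them by MPA could give these values too and was not tested. For IMPDH2 a deviating control alone is argued against too, since all 3 of its probe sets were higher with MPA than in the control, by at least 0.36. For the other 13 lower genes it stays open: their median was -0.72 with guanosine and -0.82 with MPA, as a control array high in these genes would give, although H2AC6 (0.11), MAP3K7CL (0.26) and ZNF425 (0.28) were higher with MPA. A lowering of the same genes by MPA and by guanosine, each through its own route, could give these values too and was not tested.

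The poly-A spike-in signals were lower on the MPA array by -0.29. A lower signal of all spike-ins is argued against by the hybridisation spike-ins, with a median of -0.073 and a lowest value of -0.17. A larger share of polyadenylated RNA in the total RNA of MPA-treated cells, as a drop in ribosomal RNA would give, could dilute the spike-ins, but the other 3 arrays spanned 0.27 among themselves, so it cannot be told apart from unequal amounts of spike-in added.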

How the results depend on the processing

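The 1.5-fold threshold, the raising of values below the floor and the 2 other reference arrays were chosen after seeing the data; all other settings were set beforehand. A median or gene value was taken as moved past 0.1 on the log2 scale and a count past 1.5 times. Of 94 alternative gene counts 70 stayed within this bound, as did 421 of 468 list medians, 207 of 243 named gene values and 17 of 17 values of the MPA difference with guanosine present. Of 146 alternatives for the 21 lists with a median of at least 0.2 in MPA against control, 1 changed sign, the neuron and oligodendrocyte markers at -0.0062 with the floor at the 75th percentile. With that floor, which leaves fewer genes, 121 genes were 2-fold higher with MPA, 113 higher and 110 lower with both compounds against MPA, and 0 lower with guanosine. With values below the floor raised to it, 162 were higher and 139 lower with MPA, 153 higher and 144 lower with both against MPA, and 0 lower with guanosine. At 3-fold, 45 genes were higher and 12 lower with MPA, 15 higher and 47 lower with both against MPA, and 0 lower with guanosine. At 1.5-fold, 592 were higher and 824 lower with MPA, 39 and 14 with guanosine, 50 and 18 with both against control, 966 and 523 with both against MPA, and 2 lower with both against guanosine. With the median of probe sets, 1 gene was 2-fold higher and 0 lower with guanosine, and 2 higher with both against control; with _x_at probe sets kept, 0 were lower with guanosine; after loess, 1 was higher and 1 lower. The RNA polymerase I median was -0.29 with the median of probe sets. Against the guanosine array the DNA replication median was -0.83 and the G2 and mitosis median -0.31, and against the mean of the other arrays -0.88 and -0.41; where no construction explains a shift, the cause was not tested. Loess moved the median of all genes by 0.03 in MPA against control. Signal over background limits genes near the floor of 63.0. No paired analysis was possible because each condition had 1 array, and leaving out a replicate was not possible either.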

Other observations

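The gene families below were formed and looked at only after the data were seen, and all their tests were chosen after the results were seen; no explanation was tested.

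Genes were grouped by the letters that open their symbols, which gave 131 families with at least 10 members above the floor; 20 lay below the middle 95% of matched random lists and 10 above it in MPA against control. The families of SR splicing factors and nucleoporins were among the lowest. The SR splicing factors (SRSF genes) had a median of -0.62, with 10 of 11 lower. SRSF8 had the largest measured difference, -1.43, followed by SRSF2 (-1.42) and SRSF7 (-0.95), and SRSF5 was at 0.39. In both compounds against guanosine, which shares no array with MPA against control, the SRSF median was -0.0006. The nucleoporins (NUP genes) had a median of -0.58, with 19 of 20 lower, led by NUP85 (-1.03) and NUP153 (-0.77), and the HNRNP family of RNA-binding proteins -0.43, with 10 of 11 lower, led by HNRNPAB (-0.82). After cyclic loess these medians were -0.55, -0.52 and -0.37. In both compounds against guanosine, the NUP median was -0.0093 (percentile 7.06) and the HNRNP median -0.03 (percentile 1.38). EXOSC genes at -0.38 (percentile 1.11), UTP genes at -0.34 (percentile 1.35) and DDX genes at -0.19 (percentile 0.52) lay below the middle 95% of random lists, and PRPF genes at -0.21 (percentile 7.6), LSM genes at -0.20 (percentile 13.3) and RBM genes at -0.09 (percentile 18.9) inside it.

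The HLA genes were higher in 14 of 14 cases, with a median of 0.34 (0.41 after loess) and HLA-E and HLA-DQA1 both at 0.71. Some HLA genes are close to each other in sequence, and whether their probe sets read each other's transcripts was not checked, so the 14 values are uncertain as separate evidence. Subunits of mitochondrial complex I (NDUFA genes) had a median of 0.17 with 11 of 12 higher, while the oxidative phosphorylation list fixed beforehand had a median of 0.05 over 27 genes at percentile 94.4, inside the range of random lists. The NDUFA median in both compounds against guanosine was 0.06 at percentile 99.8, with 11 of 12 higher. The matrix metalloproteinases (MMP genes) had a median of 0.33 with 9 of 11 higher and MMP3 at 0.55. Their median in both compounds against guanosine was -0.10 at percentile 0.12, with 6 of 11 lower. The histone genes with polyadenylated transcripts went apart, with H2BC21 at 2.14, from below the floor in the control, and H2BC12 at -1.43.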
